A study of Mus musculus with 4 samples.

How the data were processed

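Liver RNA from mice given DEN was measured by RNA sequencing in 4 libraries, 2 labelled Control and 2 labelled Dph1 KO. Per the labels' protocols, RNA was taken from frozen livers with Trizol and made into directional libraries with a stranded mRNA kit. The genome build was GRCm38 (mm10), per the submitters' processing notes. The aligner, the read counter, the trimming tool and whether counting used strand are not given in the sources used here. Each deposited table lists 35522 genes in the same order, and no entry lacks a gene name.

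Per the file headers, the authors gave whole-number read counts per gene, as total and uniquely matched reads over genes, exons, exon junctions and introns. Per the file headers, the tables also hold RPKM and TPM values, which the authors computed from exon reads. The deposited ratios, each a fraction from 0 to 1, give unique exon reads and intron reads as shares and were not used. Other deposited columns hold annotation, such as the number of exons and exon length. Total reads include reads that match several places, and how the authors divided these is not given in the sources used here, so members of multigene families and overlapping genes are uncertain. Uniquely matched reads were 89.3% to 90.2% of gene reads.

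The main values are total reads per gene, at 19474596 to 21137358 reads per library. Introns held 8.64% and 6.24% of reads in Control and 11.0% and 8.26% in Dph1 KO, in good part from mitochondrial genes whose reads the tables list as intron reads. The pairs of one genotype differed by more than sampling noise, with a chi-square per degree of freedom of 32.0 (Control) and 83.0 (Dph1 KO), so all 4 libraries were kept as separate samples.

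Tests used R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by genotype, scaled by TMM and compared by edgeR's quasi-likelihood test (glmQLFit, glmQLFTest) with genotype as the only term. P-values were adjusted by Benjamini-Hochberg over 13303 genes, with a threshold of 0.05, and "rose" and "fell" are used for genes past it. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM in the text are scaled by TMM factors (0.945 and 0.884 in Control, 1.16 and 1.04 in Dph1 KO). The exception is uniquely matched Dph1 reads in exons, exon junctions and introns, whose CPM use total gene reads without these factors. The spread between replicates, as the biological coefficient of variation, was 18.5%. Intervals of read ratios are 95% Clopper-Pearson intervals and, with floors of 3 counts, cover counting error only.

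Before the data were examined, the design, the alternatives, gene lists and a rule for a list of ribosomal protein genes were fixed, giving 40 lists of pathways, cell types and checks. Of 873 list entries, 3 were not matched to the tables. Lists with at least 5 tested members were tested with camera and fry from limma 3.58.1 on log2 CPM with a prior count of 2. Camera used a preset correlation of 0.01 and, as an alternative, an estimated one. Adjustment was over the 37 lists tested.

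The rule for named genes took Dph1 and the 8 genes that rose and 8 that fell most. It left out predicted, Riken and pseudogene symbols and asked for a mean of at least 1 CPM, no overlap between the genotypes and one sign in all leave-one-out fits. It added up to 3 called members of each list with the lowest p-values, or the 2 most abundant members where none was called, and the called members of the check lists. Some genes that the rule takes are not reported here, and they stay in the counts of each list. This left 109 genes, of which the text names a part. Genes outside the rule are said to be chosen after their values were seen.

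GC content came from the longest GENCODE M21 transcript of each gene, found for 20949 of 21054 protein-coding genes (99.5%). As an addition after the data were seen, a smooth trend on GC content and exon length was fitted in each library with mgcv 1.9.3 (basis size 6) and entered as an offset. The parent of each tested pseudogene was its best match among protein-coding transcripts by BLAST 2.17.0 (e-value 1e-20). Gene types came from a RefSeq gene table. DESeq2 1.42.0, limma-voom and limma-trend on log2(TPM + 1) were alternatives, with other scalings, filters, read classes and each library left out. A library left alone in its genotype is assumed to vary as the pair of the other genotype does. Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1 were used for tables and Fisher's exact tests.

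The test was checked on counts simulated from the real means and depths of these libraries, with 200 of 13102 tested genes changed. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery at lower counts was not measured. The test recovered 10.4% of genes changed 1.5-fold, 62.7% changed 2-fold and 100% changed 4-fold, with 6 false calls among 121. With no change simulated, it called 0 of 13120 genes, with the GC-corrected fit likewise. Changes near 1.5-fold are thus mostly below what 2 libraries per genotype can show. The simulations above held no GC or length trend. The simulations with the fitted trends added also took the smaller spread of the GC-corrected fit (biological coefficient of variation 15.6%, against 18.5%). Their calls thus cannot be set against those above as an effect of trends only. With these trends and no gene changed, the main test made 97 calls, all false. With trends and changed genes together, 383 of its 502 calls were false. That share holds for 200 changed genes and does not carry over to the calls of the real data.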

Results

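Liver RNA was sequenced 1 day after diethylnitrosamine (DEN), a carcinogen that liver cytochrome P450 enzymes convert into a DNA-alkylating agent. Livers labelled Control (n = 2) were set against livers labelled Dph1 KO (n = 2), all of strain C57BL/6 in the labels. Dph1 encodes a subunit of the enzyme complex that starts the synthesis of diphthamide, a modified histidine of the translation elongation factor eEF2. The comparison asks how livers labelled Dph1 KO differ from Control livers in gene expression soon after the carcinogen. Livers without DEN were not analysed here, so no value below separates a response to DEN from a standing difference between the genotypes. The Control libraries held 19474596 and 20355790 reads in genes, and the Dph1 KO libraries 20410978 and 21137358. Log2 CPM (counts scaled to a common library total) correlated across genes at Pearson r = 0.991 between the Control libraries and r = 0.977 between the Dph1 KO libraries. Between genotypes, r lay from 0.936 to 0.967, where genes are not independent replicates. The first principal component held 74.8% of the variance and separated the genotypes. The labels do not state that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

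Dph1 transcripts were lower in both Dph1 KO livers and were still present there. Dph1 (gene ID 116905; GRCm38 chromosome 11, 75177643 to 75190483) had 69.3 ± 1.40 CPM in Control and 24.7 ± 9.67 CPM in Dph1 KO (SD, n = 2 each). Its log2 fold change was -1.49 (SE 0.26; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0107). The total reads were 1292 and 1228 in Control and 421 and 689 in Dph1 KO. Dph1 overlaps Ovca2, which was not called (log2 fold change -0.24, edgeR adjusted p = 0.431), and reads in the overlap cannot be assigned to one gene for certain. Uniquely matched exon reads were 742 and 702 in Control and 162 and 252 in Dph1 KO. In CPM of gene reads without TMM scaling, the Dph1 KO mean was 27.4% of the Control mean. Uniquely matched exon junction reads gave 27.3%. Intron reads of Dph1 were few, 20 in each Control library and 32 and 39 in the Dph1 KO libraries. The sources used here do not say which part of the gene was removed or in which cells, so these reads check the labels by level only.

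**Figure D1:**
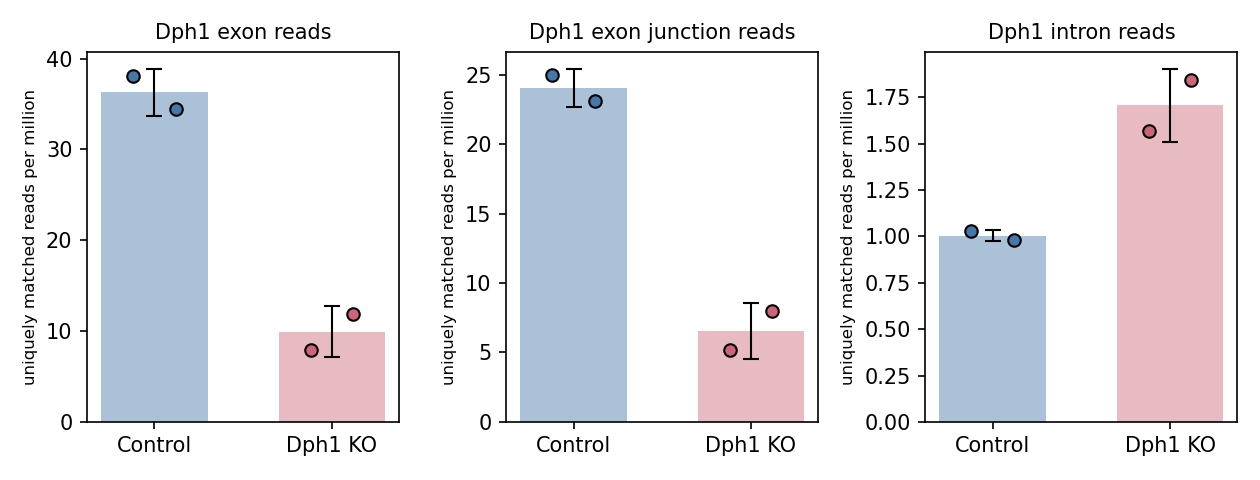
Uniquely matched Dph1 reads in CPM of gene reads without TMM scaling, in exons, across exon junctions and in introns, for Control and Dph1 KO livers. Bars show the mean, error bars the SD and points the 2 libraries of each genotype. Mean exon reads were 36.3 in Control and 9.93 in Dph1 KO, while mean intron reads were 1.00 and 1.71.

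Of 13303 genes tested, 646 rose and 994 fell in Dph1 KO livers at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). Among protein-coding genes 12.3% were called in this fit, and the counts of list members from it are to be read beside that share. Other fits called other numbers of genes over all. Their list counts (DESeq2, GC-corrected or with a library left out) are therefore not to be read beside 12.3%. The genes with the largest rises included major urinary protein genes, the haemoglobin gene Hba-a2, the class II histocompatibility gene H2-Eb1 and the acute phase gene Saa2. Those with the largest falls included the histocompatibility gene H2-Q2, the interferon-inducible GTPase gene Gvin1 and Trim12a. Of all tested genes, called or not, 67.4% had both Dph1 KO libraries on one side of both Control libraries, where chance gives 33.3% and genes are not independent. The smallest two-sided exact permutation p that 2 against 2 libraries allow is 0.333, so the calls rest on the spread shared across genes. The count depended on single libraries: it was 749 without Control replicate 1, 528 without Control replicate 2, 1330 without Dph1 KO replicate 1 and 5405 without Dph1 KO replicate 2. With 1 library of a genotype left out, the spread comes from the pair of the other genotype. These counts, and calls lost in such fits below, thus also reflect which pair is left. With no scaling beyond the library total, 77.0% of calls were rises, against 39.4% with TMM scaling, and the median log2 fold change moved by 0.26.

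The fold changes followed the GC content of the transcripts. Over 9577 protein-coding genes, the log2 fold change and GC content had a Spearman correlation of -0.66 across genes. The deviation of each gene from its mean over the 4 libraries was also correlated with GC content. The correlations were 0.58 and 0.61 in the Control libraries and -0.72 and -0.22 in Dph1 KO replicates 1 and 2. Such deviations balance out over the libraries, so a trend in 1 library forces opposite trends in others. They show differences between libraries and not which library holds a trend. In 5 equal classes of genes from low to high GC, the median log2 fold change went from 0.46 to -0.58. With a smooth GC and length trend removed from each library, a step added after the data were seen, 359 genes rose and 406 fell. Of the 1640 calls, 572 were kept with the same sign. Values after this step are called GC-corrected.

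**Figure D2:**
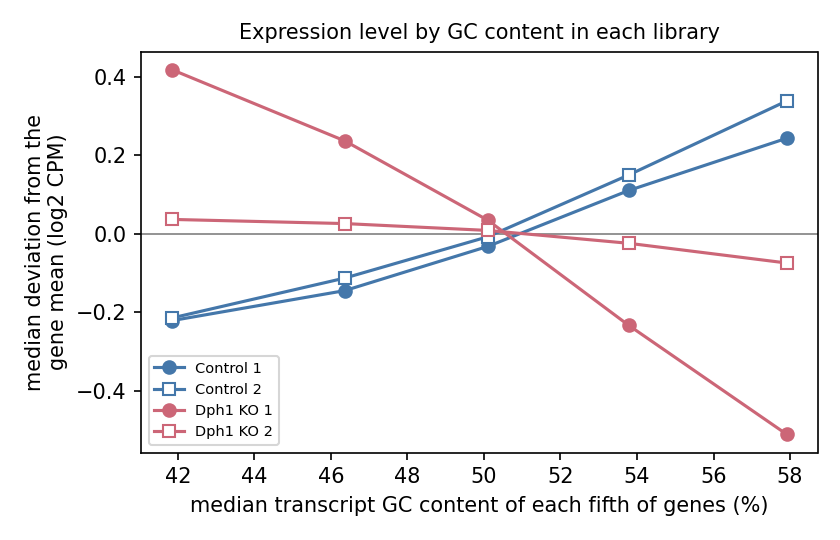
Median deviation of each gene from its mean over the 4 libraries (log2 CPM) in 5 equal classes of protein-coding genes ordered by transcript GC content (percent). Each line is a library, blue for Control and red for Dph1 KO. The deviation ran from -0.22 to 0.24 in Control replicate 1 and from 0.42 to -0.51 in Dph1 KO replicate 1.

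Several of the largest changes lay in multigene families. Hba-a2 had 1.43 ± 0.26 CPM in Control and 119 ± 8.57 CPM in Dph1 KO (SD, n = 2; log2 fold change 6.37, SE 0.28, edgeR adjusted p = 4.96e-07). Its neighbour Hba-a1 fell by 2.51 on the log2 scale. Most reads of both genes matched more than one place, but uniquely matched reads gave the same calls. Mup9 (log2 fold change 10.53) and Mup1 (4.31) rose and Mup19 (-4.17, at 76.7 and 5.03 CPM in Dph1 KO replicates 1 and 2) fell. Under 10% of the reads of these 3 genes were unique, and with unique reads alone Mup1 was not called and had a log2 fold change of -0.58. Shared reads also leave Hist1h4n and Gvin1 uncertain. Gvin1 had 180 reads in Control and 0 in Dph1 KO, at least 75.0-fold lower against a floor of 3 counts over the group. H2-Q2, on chromosome 17 at 35342333 to 35345722, had 771 reads in Control and 2 in Dph1 KO, a ratio of 482 (95% counting interval 133 to 3986, Clopper-Pearson). H2-Eb1, on chromosome 17 at 34305867 to 34316674, rose with a log2 fold change of 4.00 (SE 0.46), and leaving out 1 library gave 3.16 to 4.57, the lowest without Dph1 KO replicate 2. On chromosome 7, Trim6 rose by 3.59 and Trim12a fell by 4.94 on the log2 scale. The growth hormone gene Gh had 1 read in Control and 398 in Dph1 KO, a ratio of 318 (95% counting interval 56.8 to 12607, Clopper-Pearson), at 1.57 CPM in Dph1 KO replicate 1 and 16.5 CPM in replicate 2. Prrg1 and the calcium-binding protein gene Cib3 fell, with log2 fold changes of -3.99 each. Cib3 stood at 26.0 and 8.56 CPM in the Control libraries, and leaving out 1 library gave -4.65 to -2.98. The steroid hydroxylase gene Cyp21a1 had 1.90 and 40.3 CPM in the Control libraries, and its call (log2 fold change -4.27, edgeR adjusted p = 0.0290) was lost after GC correction and without Control replicate 2.

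Of 23 tested genes of cholesterol synthesis, 11 fell and 12 were not called, and 13 fell and 1 rose when adjusted over the list alone. Dhcr7, which catalyses the last step to cholesterol, had 245 ± 13.8 CPM in Control and 76.4 ± 19.4 CPM in Dph1 KO (SD, n = 2; log2 fold change -1.68, SE 0.25, edgeR adjusted p = 0.00444). The mevalonate pathway enzyme gene Mvd fell by 1.68 (SE 0.20) on the log2 scale. The list stood below other genes in camera, a competitive set test with a preset correlation of 0.01 (adjusted p = 0.000154; adjusted p = 0.922 with an estimated correlation). After GC correction 11 members fell and 1 rose, and camera called the list lower again, a call that was lost with an estimated correlation (adjusted p = 0.543). Leaving out 1 library at a time gave 5 to 13 falls and 0 to 2 rises, the fewest without Control replicate 1.

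Genes of fatty acid oxidation and PPAR-alpha targets also stood lower as a list (camera adjusted p = 0.00923; adjusted p = 0.922 with an estimated correlation). Of 28 tested members, 3 fell and 25 were not called, with 5 falls adjusted over the list alone. The 3 were the fatty acid omega-hydroxylase genes Cyp4a14 (log2 fold change -2.38, SE 0.32) and Cyp4a10 (-1.91, SE 0.31), close relatives that can share reads, and the lipid droplet gene Cidec (-2.06, SE 0.23). All 3 calls were kept after GC correction, and leaving out 1 library gave 3 to 7 falls, with 5 without Control replicate 1, 7 without Dph1 KO replicate 1 and 6, beside 3 rises, without Dph1 KO replicate 2. Fatty acid synthesis genes moved in both directions, with 1 rise and 3 falls among 17 (1 and 5 adjusted over the list alone). Scd1, the stearoyl-CoA desaturase gene, rose with a log2 fold change of 2.10 (SE 0.27), while the fatty acid synthase gene Fasn fell by 1.44 (SE 0.27) and the lipogenic regulator gene Thrsp fell by 1.71 (SE 0.40). After GC correction 1 rise and 1 fall remained, with the Thrsp call among those lost, and the Fasn call was lost without Control replicate 2. The fatty acid synthesis list held 1 rise and 1 fall without Control replicate 2 and 3 and 7 without Dph1 KO replicate 2. The gene of the main high-density lipoprotein protein, Apoa1, went from 29840 ± 4844 CPM to 7882 ± 2287 CPM (SD, n = 2; log2 fold change -1.92, edgeR adjusted p = 0.0161). No member of the 21 gluconeogenesis and glycolysis genes was called by edgeR, where 4 were lower at an unadjusted p under 0.05 and DESeq2 called 3 lower. Without Dph1 KO replicate 2, 1 of these genes was called higher and 6 lower, and without Control replicate 2, 1 was called higher.

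Xenobiotic metabolism genes rose more often than they fell. Of 33 tested members, 10 rose and 1 fell, with 12 rises and 4 falls adjusted over the list alone, but the list was not called by camera (adjusted p = 0.105). Cyp2a4 went from 4.27 ± 4.19 CPM to 39.9 ± 10.9 CPM (SD, n = 2; log2 fold change 3.23, SE 0.53) and Cyp2c38 rose by 3.09 (SE 0.34). Cyp2c37 rose by 1.32 (SE 0.24). These cytochrome P450 genes lie in clusters of similar copies. After GC correction 5 members rose and 1 fell, and 4 of the 11 calls were kept. Leaving out Control replicate 1 gave 5 rises and 1 fall, Control replicate 2 gave 7 rises, Dph1 KO replicate 1 gave 10 rises and 2 falls, and Dph1 KO replicate 2 gave 16 rises and 5 falls. Among 20 bile acid genes, 4 rose and 1 fell (7 and 1 adjusted over the list alone), including the transporter genes Slco1b2 (log2 fold change 1.11) and Abcc2 (1.10). None of these bile acid calls was kept after GC correction, and Slco1b2 and Abcc2 were also lost without either Control library. The bile acid counts were 1 and 1 without Control replicate 1, 2 rises without Control replicate 2 and 11 and 1 without Dph1 KO replicate 2. Cyp2c37 was lost without Control replicate 1.

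Genes of the DNA damage response were compared in several lists. Of 30 p53 target genes, 2 rose and 28 were not called, the same 2 adjusted over the list alone. Trp53inp1, a p53-induced stress gene, had a log2 fold change of 0.96 (SE 0.24) and the pro-apoptotic gene Pmaip1 of 1.21 (SE 0.30). Both calls were lost after GC correction and without Control replicate 2, Trp53inp1 also without Control replicate 1, and without Dph1 KO replicate 2 the list held 8 rises and 4 falls. The cell cycle inhibitor gene Cdkn1a, chosen after its values were seen, had 1149 ± 101 CPM in Control and 937 ± 124 CPM in Dph1 KO (SD, n = 2) and was not called (edgeR adjusted p = 0.460). Among 23 DNA repair and damage signalling genes, 2 rose and 2 fell (3 and 2 adjusted over the list alone), and none of these calls was kept after GC correction. The counts were 6 and 4 without Dph1 KO replicate 2, 1 and 1 without Dph1 KO replicate 1, and a single rise without either Control library. The checkpoint kinase gene Atr had a log2 fold change of 1.31 and the histone gene H2afx of -0.93, with GC-corrected values of 0.60 and -0.095. No cell cycle gene was called by edgeR or DESeq2 among 26 tested, and 1 was higher and 4 were lower at an unadjusted p under 0.05. Leaving out Dph1 KO replicate 2 gave 4 lower. Apoptosis genes split, with 2 rises and 2 falls among 23, the same counts adjusted over the list alone, and 3 of the 4 calls were kept after GC correction. The pro-apoptotic genes Bid (log2 fold change -1.67) and Bak1 (-1.10) fell. The apoptosis list held 2 falls and no rise without either Control library, 1 rise and 2 falls without Dph1 KO replicate 1, and 4 rises and 6 falls without Dph1 KO replicate 2.

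Integrated stress response genes stood lower as a list (camera adjusted p = 0.00923; adjusted p = 0.922 with an estimated correlation), a call that was lost after GC correction. Of 25 tested members, 5 fell and 1 rose, the same counts adjusted over the list alone. The amino acid transporter gene Slc7a5 (log2 fold change -1.70, SE 0.28), Vldlr (-1.69, SE 0.28) and the pseudokinase gene Trib3 (-1.46, SE 0.29) fell, and Trib3 was not called after GC correction. GC-corrected, 2 members of the list rose and 2 fell, while 4 fell without Control replicate 1 and 3 without Control replicate 2, 2 rose and 5 fell without Dph1 KO replicate 1, and 2 rose and 9 fell without Dph1 KO replicate 2. In the unfolded protein response list, 2 of 20 fell, the same 2 adjusted over the list alone. Derl3, which acts in degradation of misfolded proteins, fell by 3.43 (SE 0.25), and Sdf2l1 fell by 0.77 but had a GC-corrected value of -0.16 and was not called without either Control library. Without Dph1 KO replicate 2, 7 of the 20 rose and 3 fell. Of 23 NRF2 targets, 1 rose and 3 fell (1 and 6 adjusted over the list alone). The glutathione transferase gene Gsta4 fell by 1.41, while Nqo1, a quinone reductase gene, rose by 1.12 and was not called after GC correction. Gsta4 and Nqo1 were both lost without Control replicate 2, Nqo1 also without Dph1 KO replicate 1, and 1 of the 4 calls of the list was kept after GC correction. With Dph1 KO replicate 2 left out, 3 of the 23 rose and 12 fell, and with Control replicate 2 left out, 1 fell. Of 14 heat shock genes, 1 rose and 1 fell, the same counts adjusted over the list alone, and neither was called after GC correction or without Control replicate 1. A single fall was called without Control replicate 2, a single rise without Dph1 KO replicate 1, and 2 rises and 3 falls without Dph1 KO replicate 2.

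The diphthamide pathway list held 9 tested genes, of which 2 fell and 7 were not called, the same counts adjusted over the list alone. Besides Dph1, the eEF2 kinase gene Eef2k fell by 1.17 (SE 0.21; edgeR adjusted p = 0.0114), a call that was lost without Control replicate 2. The eEF2 gene itself, Eef2, chosen after its values were seen, was not called (log2 fold change -0.73, edgeR adjusted p = 0.112). Cytosolic ribosomal protein genes stood lower as a list (camera adjusted p = 5.25e-05; adjusted p = 0.922 with an estimated correlation), with 4 of 82 falling and 0 called adjusted over the list alone. At an unadjusted p under 0.05, 26 were lower and 1 was higher, and DESeq2 called 22 lower. Of all 13303 tested genes, 4549 had an unadjusted p under 0.05, a share no lower than that of the list, and 1640 were called. The 4 calls were lost without Control replicate 2, while 2 genes fell without Control replicate 1, 4 fell and 2 rose without Dph1 KO replicate 1, and 47 fell and 1 rose without Dph1 KO replicate 2. The list median log2 fold change was -0.42, and -0.15 after GC correction, where 2 of the 4 calls were kept and camera called the list lower again (adjusted p = 0.0487; adjusted p = 0.543 with an estimated correlation). Rpl28 (log2 fold change -1.25), Rps16 (-1.23) and Rps28 (-1.16) fell, but under 10% of their reads were unique. Rps16 had a log2 fold change of -0.33 with unique reads and was not called, and Rpl28 was not called after GC correction. Over the whole list unique reads called 1 higher and 8 lower, with a median of -0.37. Of 26 ribosome biogenesis genes, 4 fell, the same number as adjusted over the list alone, led by Rrp9 (log2 fold change -1.44), and Rrp9 alone was called after GC correction. In this list 2 fell without Control replicate 1, 1 without Control replicate 2, and 5 fell and 2 rose without Dph1 KO replicate 2. Of 27 translation factor genes, 2 fell, the same 2 adjusted over the list alone. These were Eif6 (log2 fold change -1.40), which keeps ribosomal subunits apart, and Eif4ebp1 (-0.97), an inhibitor of cap-dependent initiation. The translation factor list had a median of 0.09 and a mean of -0.10, was not called by camera (adjusted p = 0.752) and was called lower after GC correction, though not with an estimated correlation (adjusted p = 0.543). Eif6 was lost without Control replicate 2, and Eif4ebp1 without either Control library, while without Dph1 KO replicate 2 the list held 6 rises and 7 falls.

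Clock genes changed in opposite directions. Of 17 tested members, 3 rose and 4 fell (4 and 5 adjusted over the list alone), and all 7 calls were kept after GC correction. The clock list held 2 rises and 3 falls without Control replicate 1, 3 and 3 without Control replicate 2, and 3 and 7 without Dph1 KO replicate 2. The core activator genes Arntl and Clock rose with log2 fold changes of 2.14 (SE 0.38) and 1.64 (SE 0.26), and the output regulator gene Dbp fell by 2.08 (SE 0.35). The labels used here give no hour of tissue collection. Among acute phase genes, 3 of 23 rose and 2 fell (6 and 2 adjusted over the list alone), and after GC correction 2 rose and 1 fell, with 3 of the 5 calls kept. Saa1 and Saa2, which share sequence, rose with log2 fold changes of 2.02 and 3.35, and Saa2 stood at 81.5 CPM in Dph1 KO replicate 1 and 475 CPM in replicate 2. Orm3 fell by 2.97 (SE 0.26). Without Dph1 KO replicate 1, 9 acute phase genes rose and 1 fell, and without Dph1 KO replicate 2, 6 rose and 7 fell. Among 27 interferon-stimulated genes, 2 rose and 1 fell (2 and 2 adjusted over the list alone), and 1 of the 3 calls was kept after GC correction. All 3 interferon calls were lost without Control replicate 2, while 1 rose without Control replicate 1, 4 rose and 1 fell without Dph1 KO replicate 1, and 4 rose and 4 fell without Dph1 KO replicate 2. Camera called neither the acute phase list (adjusted p = 0.361) nor the interferon list (adjusted p = 0.105), and called both higher after GC correction. With an estimated correlation both GC-corrected calls were lost (adjusted p = 0.831 and 0.543). Among 20 NF-kB and inflammatory genes, the chemokine gene Cxcl1 rose (log2 fold change 1.38, the only call over the list alone as well) and was not called after GC correction or without Control replicate 2, where 1 other gene fell, while 1 rose and 5 fell without Dph1 KO replicate 2.

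Markers of liver zones and of other cell types moved in part. Of 19 pericentral hepatocyte genes, 3 rose and 3 fell, the same counts adjusted over the list alone, and of these 6 calls Oat (log2 fold change 0.97) and Rgn (1.34) were kept after GC correction. Oat was lost without either Control library and Rgn without Control replicate 1. The pericentral list held 1 rise and 2 falls without Control replicate 1, 2 rises without Control replicate 2 and 5 and 5 without Dph1 KO replicate 2. Of 20 periportal genes, 1 rose and 2 fell, the same counts adjusted over the list alone, with Cyp17a1 at 2.71 and Hsd17b6 at -1.18, the latter lost without Control replicate 2. After GC correction 2 of the 3 periportal calls were kept, and the list held 3 rises and 2 falls without Dph1 KO replicate 1 and 2 and 5 without Dph1 KO replicate 2. Stellate cell and fibroblast genes held 1 rise and 5 falls among 18 (2 and 7 adjusted over the list alone). Acta2, a marker of contractile cells (log2 fold change -2.16, SE 0.26), and Tagln (-1.25, SE 0.28) fell, and after GC correction 2 of the 6 calls were kept. The stellate list held 3 falls without Control replicate 1 or Dph1 KO replicate 1, 2 without Control replicate 2, and 4 rises and 7 falls without Dph1 KO replicate 2. Of 16 endothelial genes, 3 fell, the same number as adjusted over the list alone, including Vwf (log2 fold change -1.17) and Stab1 (-0.90), and Stab1 was lost without either Control library, where the endothelial list held 1 fall, and 2 of the 3 calls were kept after GC correction. Of 12 cholangiocyte and progenitor genes, Krt23 fell (log2 fold change -2.86; 4 falls adjusted over the list alone), and 2 fell without Dph1 KO replicate 1 and 4 without Dph1 KO replicate 2. Of 7 B and plasma cell genes, the immunoglobulin joining chain gene Igj (-2.19) and Cd79a (-1.32) fell (3 adjusted over the list alone), and Cd79a was not called after GC correction or without any 1 of Control replicates 1 and 2 and Dph1 KO replicate 1. The last 2 lists stood lower in camera (adjusted p = 0.00923 each; adjusted p = 0.922 each with an estimated correlation). Of 19 macrophage and Kupffer cell genes, Cd68 fell by 1.18 and Mpeg1 rose by 0.66 (1 rise and 2 falls adjusted over the list alone), and Mpeg1 was not called after GC correction or without either Control library. Leaving out Dph1 KO replicate 1 gave 2 rises and 1 fall, and Dph1 KO replicate 2 gave 1 rise and 7 falls. No gene of 5 tested for T and NK cells, 3 for adipose and mesothelium or 2 for pancreatic acinar tissue was called by edgeR or DESeq2, and 1 of them, in the T and NK cell list, had an unadjusted p under 0.05. In that list 1 gene was called higher without Dph1 KO replicate 1. GC-corrected, 1 pancreatic gene was called higher.

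Camera called 6 of 37 lists, and none of the 37 with an estimated correlation, where no list had an unadjusted p under 0.05. With the preset correlation, camera called 1 list in counts simulated from the GC and length trends with no gene changed. It called 3 lists when 200 genes were changed as well, taken at random from those with a mean of at least 5 CPM. After GC correction it called 0 in either simulation. The self-contained test fry called 2 lists lower by its PValue, which asks whether genes move on balance one way: ribosome biogenesis (adjusted p = 0.0132) and stellate cells and fibroblasts (adjusted p = 0.0223). Its PValue.Mixed, which asks whether genes change in either direction, called 18 lists. Neither fry value compares a list with other genes. With no scaling beyond the library total, the median of the ribosome biogenesis list moved from -0.099 to 0.17 and that of the stellate list from -0.24 to 0.026. After GC correction camera called 8 lists, and none of the 37 with an estimated correlation, where no list had an unadjusted p under 0.05. Without Dph1 KO replicate 2 camera called 3 lists. Besides translation factors, the median, mean and camera direction differed in sign for the unfolded protein response, macrophage, erythroid, fatty acid synthesis, apoptosis, periportal and urea cycle lists. The number of called members moved by more than 1.5 times in 22 of 40 lists without Control replicate 1, in 26 without Control replicate 2, in 13 without Dph1 KO replicate 1 and in 28 without Dph1 KO replicate 2. The fold of 21 of the 98 called genes chosen for naming moved by more than 1.5 times when 1 library was left out.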

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

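All the values below were looked at after the data were seen. They come from intron reads, a read class that the comparisons do not use on its own, and each lies above both Control livers.

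Intron reads, without the 10 genes that hold most of them (mainly mitochondrial genes), made up 5.32% of gene reads in Dph1 KO replicate 1 and 4.25% in replicate 2. The Control libraries had 3.63% and 2.96%. With 2 libraries per genotype, no two-sided exact permutation test of this difference can go below 0.333.

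Uniquely matched intron reads of Dph1 stood at 1.57 CPM in Dph1 KO replicate 1 and 1.85 in replicate 2, against 1.03 and 0.98 in the Control libraries. These rest on 32, 39, 20 and 20 reads. The uniquely matched exon reads of the gene went the other way, with the Dph1 KO mean at 27.4% of the Control mean, while intron reads were at 170%. These CPM and percentages use total gene reads without TMM factors. Those factors were larger in Dph1 KO (1.16 and 1.04) than in Control (0.945 and 0.884). Scaling by them would make the intron rise smaller, and the scaled percentage was not computed.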

How the results depend on the processing

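The GC corrections and the protein-coding restriction were chosen after the data were seen; the other alternatives were planned. The count of 1640 called genes stayed between 1353 and 2233 with RLE factors, TMM without the 50 most abundant genes, no filter, a stricter filter, DESeq2, limma-voom, unique reads, exon reads, GC correction alone and protein-coding genes alone. The genes called were not all the same. GC correction alone kept 866 of the 1640 calls with their sign (52.8%), and the other settings of this range kept 82.6% to 99.6%. It was 3423 with no scaling (2634 up, 789 down), 2986 with limma-trend on TPM (2414 up, 572 down; median shift 0.33), 765 with GC and length trends removed, 887 with at least 2-fold change and 3398 at an adjusted p of 0.1. Leaving out 1 library gave 528 to 5405 calls: 749 without Control replicate 1, 528 without Control replicate 2, 1330 without Dph1 KO replicate 1 and 5405 without Dph1 KO replicate 2. Camera called 6 lists, 0 with an estimated correlation, and 3 to 8 with 1 library left out, with 3 without Dph1 KO replicate 2. Fry, which asks another question, called 2 lists, neither of them among those 6. Stricter thresholds call fewer genes by construction; the cause of the other shifts was not tested. Of the named genes, 36 of 109 lost their call with GC and length trends removed, 32 without Control replicate 1, 43 without Control replicate 2 and 9 without Dph1 KO replicate 1. Of these 109 named genes, only the 98 called in the main fit had a call to lose. The log2 fold change turned for Mup1 with unique reads (-0.58). It turned with no scaling and with TPM for Ccnd1 (0.14, 0.23) and Il2rb (0.075, 0.13). With GC and length trends removed it turned for Ddx3y (-0.091) and Il2rb (0.077), and with the GC trend alone for Ddx3y (-0.023), Il2rb (0.077) and Car3 (-0.064). With 1 library left out it ran from -0.15 to 0.54 for Car3, below 0 without Control replicate 1, and from -0.50 to 0.14 for Il2rb, above 0 without Control replicate 1 or Dph1 KO replicate 1. None of these reversed values was called. No paired analysis was possible because the labels give no replicate numbers that the genotypes share.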

Other observations

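The tests of GC and length trends and of reads shared between copies were chosen after the results they bear on were seen, as were the definition of switched genes and the widths of 1 and 5 Mb around pseudogene parents, and the counting interval for the 97 calls simulated from trends alone was added after that value was seen to lie below its bound.

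Sex-biased liver genes changed in both directions. Of 18 male-biased genes, 5 rose and 2 fell (7 and 3 adjusted over the list alone), among them Elovl3 (log2 fold change 2.07) and Hsd3b5 (1.38) upward and Cyp4a12b (-3.00) and Serpina1e (-1.46) downward, where Hsd3b5 and Serpina1e were lost without Control replicate 1 and Serpina1e also without Control replicate 2. In the male-biased list 5 of the 7 calls were kept after GC correction, with 2 rises and 2 falls without Control replicate 1, 4 and 1 without Control replicate 2, 4 and 6 without Dph1 KO replicate 1, and 7 and 2 without Dph1 KO replicate 2. Of 7 female-biased genes, 3 rose and 1 fell, the same counts adjusted over the list alone, with Cyp2b9 at 2.58 and Acot3 at -2.50, the latter not called after GC correction. The Y-linked genes Eif2s3y (0.83) and Kdm5d (0.88) were called higher in Dph1 KO (2 of 4 in the Y-linked and Xist list, and 2 adjusted over the list alone), and neither was called after GC correction or without any 1 of Control replicates 1 and 2 and Dph1 KO replicate 1, while all 4 were called higher without Dph1 KO replicate 2. Among erythroid genes, 1 of 5 rose and 2 fell, the same counts adjusted over the list alone, and 2 of the 3 calls were kept after GC correction, with 1 fall in place of 2 without any 1 of Control replicates 1 and 2 and Dph1 KO replicate 1. Of 5 neutrophil genes, Ltf rose (0.99; 1 rise and 1 fall adjusted over the list alone), a call that was lost without either Control library, and 1 rose and 1 fell without Dph1 KO replicate 2. Of 11 oncofetal and liver cancer marker genes, Golm1 rose (1.05) and Akr1b8 fell (-1.07; 3 and 1 adjusted over the list alone), and neither was called after GC correction or without either Control library, while 1 other gene rose without Control replicate 2, and 2 rose and 1 fell without Dph1 KO replicate 1. Of 23 hepatocyte secreted protein genes, F9 rose (0.89; not called after GC correction) and Apoa1 fell, the same counts adjusted over the list alone. Only Apoa1 was called in this list without either Control library, 3 rose and 1 fell without Dph1 KO replicate 1, 4 and 2 without Dph1 KO replicate 2, and DESeq2 called 4 higher and 4 lower. Of 20 urea cycle and amino acid genes, Oat alone rose, also over the list alone. Its call was lost without either Control library, while 3 rose without Dph1 KO replicate 1, and 1 rose and 6 fell without Dph1 KO replicate 2.

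Called genes. Among possible reasons for the 1640 calls, animals of different sex were tested first: all 4 libraries had Y-linked reads (Ddx3y at 11.1 CPM or more) and almost no Xist (at most 0.205 CPM), and Ddx3y had a log2 fold change of 0.57, which argues against animals of different sex. With exon reads alone, 89.9% of the calls kept their sign and call, so reads counted in introns did not drive most calls. Exon reads were already 89.0% to 93.8% of gene reads, and unspliced RNA gives reads in exons too. The comparison therefore cannot decide on unspliced RNA as a source. Removing the smooth GC and length trends left 572 calls in place. Their median size was 1.14 and their median SE 0.19 on the log2 scale. As they were picked by the corrected test, a size well above the SE was fixed in advance and excludes nothing. GC or length effects that the smooth fit misses stay possible for them. For the other 1068 calls, the median size went from 0.96 (SE 0.24) to 0.49 (SE 0.17) with the sign kept in 1062, so the smaller fold ended most calls, and trend and genotype cannot be told apart. Trends alone, simulated once on unchanged genes, gave 97 calls, below 10% of the lost ones (106.8). A 95% counting interval (78.7 to 118) holds that bound, but it treats calls as independent and does not cover the spread between simulations. Trends with changed genes gave 383 false calls among 502. Loss of Dph1 stays an open and untested explanation for kept and lost calls alike.

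Switched genes. Of the calls, 73 genes (24 up, 49 down) differed by at least 8-fold with a mean of at least 1 CPM in the higher genotype, and 29 of these were pseudogenes, while 9 lay on chromosome 17 from 33 to 37 Mb, around the histocompatibility genes, such as H2-Q2, H2-Eb1 and, chosen after its values were seen, H2-K2. Reads divided between near-identical copies are argued against for the 55 that were called with unique reads, with the exception of Mup19. Mup19 rests on 18 and 14 unique reads in Control and 4 and 1 in Dph1 KO and stays uncertain. Divided reads could explain part of the other 18, of which 17 had under 10% of unique reads. Among all tested genes with under 10% of unique reads, Mup19 included, 18 of 222 were switched, against 55 of 13081 others (two-sided Fisher exact p = 1.2e-16). A candidate explanation is that the genotypes differ in segments of strain origin, with variants in parent genes moving reads to or from their pseudogenes. Under it, parents of switched pseudogenes should lie near other switched genes: 7 of 20 did within 2 Mb, against 15 of 95 other parents (two-sided Fisher exact p = 0.0617), a difference that does not pass, with p = 0.306 within 1 Mb and 0.0235 within 5 Mb. The segment of chromosome 17 from 33 to 37 Mb, with its 9 switched genes, held 147 tested genes. These 9 include Cyp21a1, whose call was lost after GC correction. Of 25 switched pseudogenes with a parent, 10 had it on chromosome 17 from 24 to 43 Mb, from 7 parents. Among these 10, Cyp4f41-ps and H2-K2, chosen after their values were seen, themselves lie in that segment. They are 76.6% and 93.75% identical to their parents Cyp4f17 and H2-T23, so they bear less on reads moving between copies. No test was made of either segment. The labels name C57BL/6 for all 4 livers, so strain origin stays undecided, and loss of Dph1 was not tested as an explanation.

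Genes near Dph1. Flanking DNA carried with a targeted allele would raise the share of called genes around Dph1. Within 10 Mb, 25 of 272 tested genes were called (9.19%), against 12.4% elsewhere (odds ratio 0.716, 95% interval 0.453 to 1.09, two-sided Fisher exact p = 0.135). No excess was seen there, nor within 5 Mb (9.03%) or 20 Mb (10.3%). After GC correction the odds ratio was 1.13 (0.530 to 2.16) within 5 Mb, 0.888 (0.477 to 1.53) within 10 Mb and 0.866 (0.533 to 1.34) within 20 Mb. A change in a few neighbours is not excluded.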
